A study of Miniopterus schreibersii with 14 samples.

How the data were processed

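Messenger RNA was sequenced from 14 dissected pieces of the autopod, the part of the limb that forms the hand or foot, of embryos of the bent-wing bat. Per the labels' protocols, total RNA was treated with DNase and made into TruSeq libraries. The submitters' processing notes name CASAVA 1.8, RSEM and edgeR, without giving their role or order. How the transcripts were assembled, and whether each library held 1 embryo or several, is not given in the sources used here, nor is whether parts of 1 stage share an embryo.

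The deposited table holds a score for each of 64618 assembled components in each library, and these scores are whole numbers that sum to between 9191852 and 11045040 per library. They are normalized counts rounded to whole numbers rather than raw counts, since in every library the low scores fell only on rounded multiples of 1 step. The step, which is the score of 1 read, lay between 1.29 and 2.23. It was chosen so that 100% of the nonzero scores up to 2000 in a library matched, which the fit thus set in advance. A match means that the score equals a whole number of steps after rounding. Over all nonzero scores, with the larger ones that the fit did not use, 99.983% to 100% matched per library. The libraries held 4550754 to 7648427 reads. Rounding of the scores kept these reads outside the tolerance set for count models, so no negative binomial count model was fitted to them. They were used with limma voom, an alternative that models log counts with weights. Intervals on single values are exact 95% intervals and cover counting error only, as does the floor of 3 reads over a group used where all its libraries were at 0.

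Components are named by assembly number, and the table does not pair them with genes. None of the identifiers matched the table of gene names used here, which lists 22775 genes (0 matches). The 27 gene lists chosen before the data were examined, their set tests, and the naming of genes by symbol were therefore not run. Identifiers took the place of symbols under the same rule, which takes the largest log2 differences among called components with the same sign in every matched pair. At most 2 components per direction and comparison are named by this rule. Named besides are comp1195_c0 and comp3354_c0, for their parallel values. A component can be a whole transcript or a piece of one, so counts of components are not counts of genes.

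Every library is a different part or stage, so no part had a replicate library. Parts were matched into 6 pairs between forelimb and hindlimb, and into 3 pairs between digit and interdigital tissue. Most tests ask whether a difference recurred over matched parts, and the matching comes from the anatomy in the labels. The stage test is not matched and takes the different parts of 1 stage as its replicates. The wing test sets the wing region against the average of the thumb side and the foot within each tissue. In the later limb pairs, forelimb parts II-V stand against hindlimb parts I-V, which include digit I. p-values measure the spread between these parts. Differences between embryos and between libraries may enter that spread or the tested difference, and cannot be told apart from differences between parts. No part has a repeat library, so the spread within 1 part was not measured.

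Differences were tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(score + 1), with the matched part as a block. The stage comparison had limb as a covariate instead. Components with a mean score of at least 10 over the 14 libraries were kept, which left 20429 components that held 98.95% of all scores. Adjusted p-values are Benjamini-Hochberg over the kept components, two-sided, and a component was called at an adjusted p under 0.05. Fold changes are on the log2(score + 1) scale, which understates the change of low components. Comparisons of 1 library with 1 have no test. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the reads, the detection counts and the plots.

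The tests and most alternatives were chosen before the data were examined. The alternatives were pseudocounts of 0.25 and 5, no filter, upper-quartile scaling, median-centred libraries, robust variance shrinkage, no block, leaving out each pair or library in turn, and other references. Chosen after seeing the data were limma voom on the recovered reads, the covariance of limb differences and its swaps, the stage change within each limb, the comparison of fetal with earlier change over separate libraries, detection at equal depth, and 2 alternatives for the fetal comparison.

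The tests were tried on simulated reads with the real depths, means from the fit and a modelled spread, in which 200 of 20429 components were changed. These 200 were drawn above a higher minimum mean score than the filter, so the shares do not cover the weakest kept components. The modelled spread can differ from the real one. The simulation was revised once to let the spread differ between components, and the values here are from the revised form. For the 6 limb pairs, 63.2% of 2-fold, 93.9% of 4-fold and 98.5% of 8-fold changes were called. For digit against interdigital tissue the shares were 57.4%, 98.5% and 100%, and for the wing region 45.6%, 86.4% and 100%. For the S14 limb comparison they were 29.4%, 80.3% and 97%, and for the limb by stage interaction 13.2%, 68.2% and 81.8%. Anterior against posterior gave 2.9%, 57.6% and 75.8%, the stage comparison 76.5%, 95.5% and 100%, and the fetal comparison 14.7%, 56.1% and 95.5%. Between 1.8% and 7.6% of calls in these simulations were false. The shares apply where about as many components changed, since the adjusted threshold depends on how many do.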

Results

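The 14 libraries cover 3 periods of limb development. At stage S14, forelimb and hindlimb buds were each divided into anterior, middle and posterior parts, giving 6 libraries. At stages S15-17, another 6 libraries held forelimb digit I, the interdigital tissue between digits I and II, forelimb digits II-V, the interdigital tissue between them, hindlimb digits I-V and hindlimb interdigital tissue. The last 2 held fetal metacarpals II-V and metatarsals I-V. Digits II-V and the tissue between them form most of the bat wing, while digit I and the foot stay small and free. The comparisons set wing-forming parts against their counterparts in the foot and on the thumb side. Each part had 1 library, at 4550754 to 7648427 reads.

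The libraries fell apart by period, each of which holds its own kind of dissected part, more than by limb. The first principal component of log2 scores held 57.9% of the variance and set the fetal libraries, at 206.8 and 231.8, apart from all earlier ones. The second held 13.9% and parted S14 from S15-17. Across components, the median Pearson r between libraries was 0.966 within S14, 0.963 within S15-17 and 0.929 between these periods. It fell to 0.69 between S14 and fetal and 0.762 between S15-17 and fetal libraries, with 0.932 between the fetal pair. Components are not independent replicates, so these r describe the libraries only. The 10 most abundant components took 13.26% of the score in metacarpals and 12.64% in metatarsals, against 4.9% to 5.81% in the earlier libraries.

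**Figure D1:**
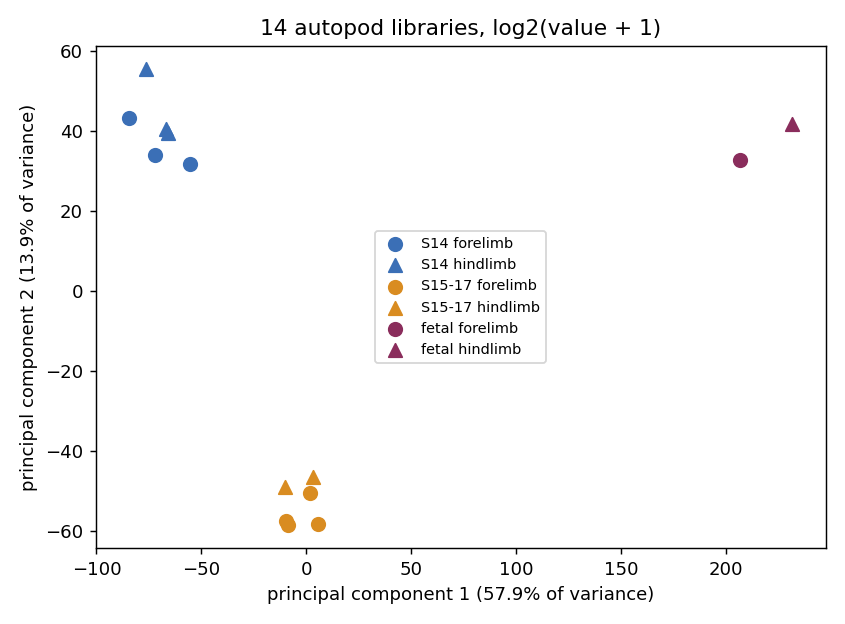
Scores of the 14 libraries on the first and second principal components of log2(score + 1) over the kept components; colour gives the stage and marker shape the limb. The fetal libraries lie at 206.8 and 231.8 on the first component, which holds 57.9% of the variance.

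Forelimb and hindlimb differed over the 6 matched pairs, which run from the bud to the fetal skeleton, in a small set of components. Component comp3938_c0 was present in forelimb and nearly missing from hindlimb, with a mean score of 382 ± 132 (SD, n = 6) against 2.83 ± 3.71 (SD, n = 6). It held 1299 reads in the 6 forelimb libraries and 11 in the 6 hindlimb libraries, a ratio of 121 (95% interval 67.3 to 243). In the opposite direction, comp3599_c0 had a mean of 1440 ± 684 in hindlimb and 2.83 ± 3.13 in forelimb (SD, n = 6 each), a ratio of 504 (274 to 1050). A second, less abundant component of each kind behaved alike: comp14042_c0 held 177 forelimb and 1 hindlimb reads, and comp13294_c0 held 162 hindlimb and 2 forelimb reads.

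In limma, 15 components were called over the 6 pairs, 6 higher and 9 lower in forelimb, and each of the 15 had the same sign in all 6 pairs, for which the test selects. The log2 difference of comp3938_c0 was 7.04 (SE 0.53, adjusted p = 0.00048) and that of comp14042_c0 was 5.19 (SE 0.40, adjusted p = 0.00048). For comp3599_c0 it was -8.67 (SE 0.42, adjusted p = 9.8e-06) and for comp13294_c0 it was -5.01 (SE 0.46, adjusted p = 0.0019). The remaining 11 ranged from at least 23.2-fold higher in pooled forelimb reads to 13.5-fold higher in pooled hindlimb reads. In digit I and the adjacent interdigital tissue of the forelimb, which were not part of the test, comp3938_c0 scored 404 and 493 and comp3599_c0 scored 21 and 26. The count was 8 without the anterior bud pair, 6 without the middle, 7 without the posterior, 9 without the digits and 9 without the interdigital pair; between 6 and 10 of the 15 stayed called without 1 pair. Voom on recovered reads called 142 components, among them all 15; a pseudocount of 0.25 or no filter gave 8, the later stages alone 8, of which 4 were among the 15, and a fit without the block 6.

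**Figure D2:**
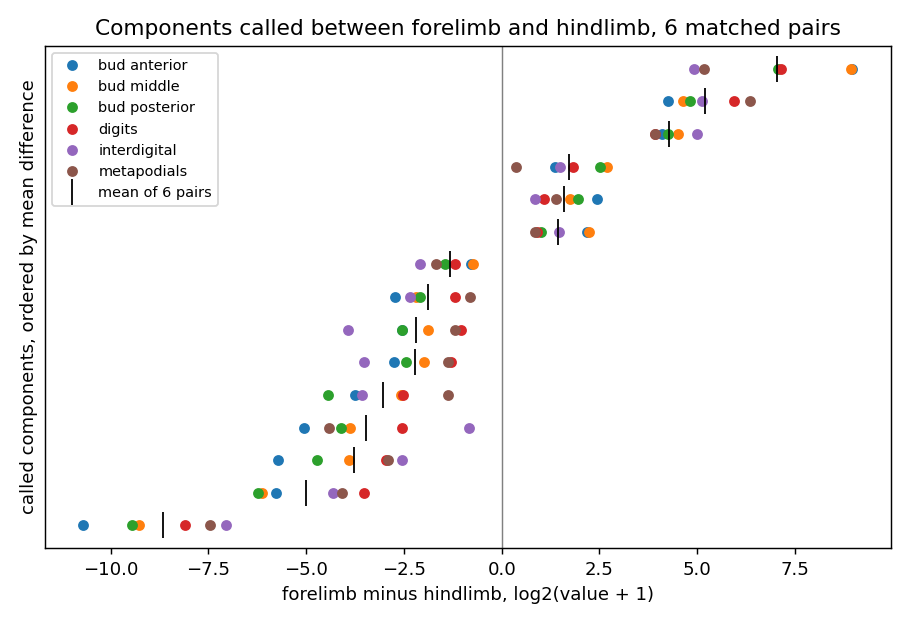
Forelimb minus hindlimb difference of log2(score + 1) for the 15 called components; each row is a component, each coloured point 1 of the 6 matched pairs and the black tick their mean. Mean differences run from 7.04 to -8.67, and every point of a component lies on the same side of 0.

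Over all kept components, the sharing of limb differences between parts was weak. Of these, 847 (4.15%) had the same sign in all 6 pairs, where 3.1% would if pairs were independent, and 832 (4.08%) did without the 15 called ones. Swapping the limbs within pairs gave as many in 6 of 32 cases, with up to 1556 components (exact one-sided p = 0.188). The covariance of the forelimb minus hindlimb log2 difference, averaged over the 15 pairings of pairs, was 0.0446. It was 0.1036 among the S14 pairs, 0.0539 among later pairs and 0.0219 across the 2 periods. The S14 pairings ran from 0.025 (anterior with middle) to 0.19 (anterior with posterior). The 9 pairings across periods ran from -0.074 (anterior bud with interdigital) to 0.081 (posterior bud with digits). Posterior bud with interdigital gave -0.048 and middle bud with metapodials -0.031, and the other pairings across periods were positive. Of the 32 ways to swap limbs within pairs, the real one gave the largest mean covariance (exact one-sided p = 0.031, the smallest this design can give), and the highest other value was 0.0379. When every swap, the real grouping included, was computed without its own 15 leading components, the real one gave 0.0324 and the highest other 0.0371 (exact one-sided p = 0.062). These tests were chosen after seeing the data.

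Within the S14 buds alone, the anterior, middle and posterior pairs shared the sign of the limb difference in 31.97% of kept components, against 25% if pairs were independent. The components that led the 6-pair comparison had wide differences in the buds, which are part of that comparison. In the anterior, middle and posterior pairs the log2 difference was -10.7, -9.27 and -9.45 for comp3599_c0 and 8.96, 8.94 and 7.07 for comp3938_c0. With 3 pairs, neither comp3599_c0 nor any other component passed the test. The simulated share of 97% for 8-fold changes thus does not describe this comparison. limma called 0 of 20429 components in the 3 bud pairs, with a smallest adjusted p of 0.0561, and 2187 had an unadjusted p under 0.05. Leaving out any 1 pair also gave 0. The count rose to 150 with robust shrinkage, 211 with voom on recovered reads, 11 with median-centred libraries, 8 without the block and 2 with a pseudocount of 5.

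The limb difference itself changed between periods for 2 components. Component comp4463_c0 was lower in forelimb at S14, with a mean log2 difference of -2.88 ± 0.85 (SD, n = 3 pairs), and higher later, at 2.09 ± 0.58 (SD, n = 3 pairs). Its scores in the anterior bud were 150 in forelimb and 1825 in hindlimb, while interdigital tissue II-V had 1399 against 268 in the foot. Component comp3957_c0 was higher in forelimb by 0.99 ± 0.14 at S14 and by 3.96 ± 0.35 later (SD, n = 3 pairs each). In anterior, middle and posterior buds it scored 210, 537 and 450 in forelimb and 96, 298 and 226 in hindlimb. Forelimb digits and interdigital tissue II-V, at 456 and 375, stayed within that forelimb range. Their hindlimb counterparts, at 26 and 19, lay below every bud score. Metacarpals scored 129 and metatarsals 10. The wider later difference thus went with lower hindlimb scores, not with a rise in the wing. The thumb side, which was not in these pairs, had other values: comp3957_c0 scored 28 in digit I and 16 in interdigital tissue I-II, against 26 and 19 in the foot, and comp4463_c0 scored 156 in digit I against 154 in hindlimb digits and 457 against 268 in interdigital tissue. The limb by stage interaction in limma was 4.97 (SE 0.43, adjusted p = 0.0071) for comp4463_c0 and 2.97 (SE 0.29, adjusted p = 0.011) for comp3957_c0, and no other component was called. A total of 1742 had an unadjusted p under 0.05. The count was 7 without the middle bud pair, 1 without the metapodials pair, and 0 without the posterior bud pair, without the interdigital pair, with no filter and with no block. Component comp3957_c0 lost its call without the anterior bud (limma adjusted p = 0.071), posterior bud (0.21), digits (0.067) or interdigital pair (0.079), and comp4463_c0 without the posterior bud (0.093), interdigital (0.079) or metapodials pair (0.12). The interactions themselves stayed between 2.84 and 3.04 for comp3957_c0 and between 4.78 and 4.86 for comp4463_c0 in these fits, which hold fewer pairs.

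Digit and interdigital tissue at S15-17 differed in 4 components, all higher in digits. Component comp10215_c0 averaged 460 ± 147 in the 3 digit libraries and 82 ± 41.1 in the 3 interdigital libraries (SD). Component comp2806_c0 averaged 496 ± 196 against 106 ± 35.9. The difference recurred on the thumb side, in the wing region and in the foot. In limma with the region as block, comp10215_c0 differed by 2.54 on the log2 scale (SE 0.18, adjusted p = 0.031) and comp2806_c0 by 2.2 (SE 0.17, adjusted p = 0.031), and 1746 components had an unadjusted p under 0.05. The count fell to 0 without the wing pair, without the foot pair, with a pseudocount of 0.25, with no filter and with no block. It was 35 without the digit I pair, 31 with a pseudocount of 5, 148 with median-centred libraries, 213 with robust shrinkage and 218 with voom, and most of these were higher in digits.

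Interdigital libraries held a wider range of components than digit libraries. At an equal depth of 4550754 reads, 45258, 44976 and 45879 components were detected in interdigital tissue I-II, interdigital tissue II-V and the foot. The matched digit libraries had 41178, 43277 and 41139. The difference averaged 3506.3 ± 1599.6 components (SD, n = 3 regions) and was positive in all 3, for which an exact two-sided test gives p = 0.25, the smallest possible with 3 regions. S14 buds had 37561 to 40323 and the fetal metacarpals and metatarsals 46151 and 43686.

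**Figure D3:**
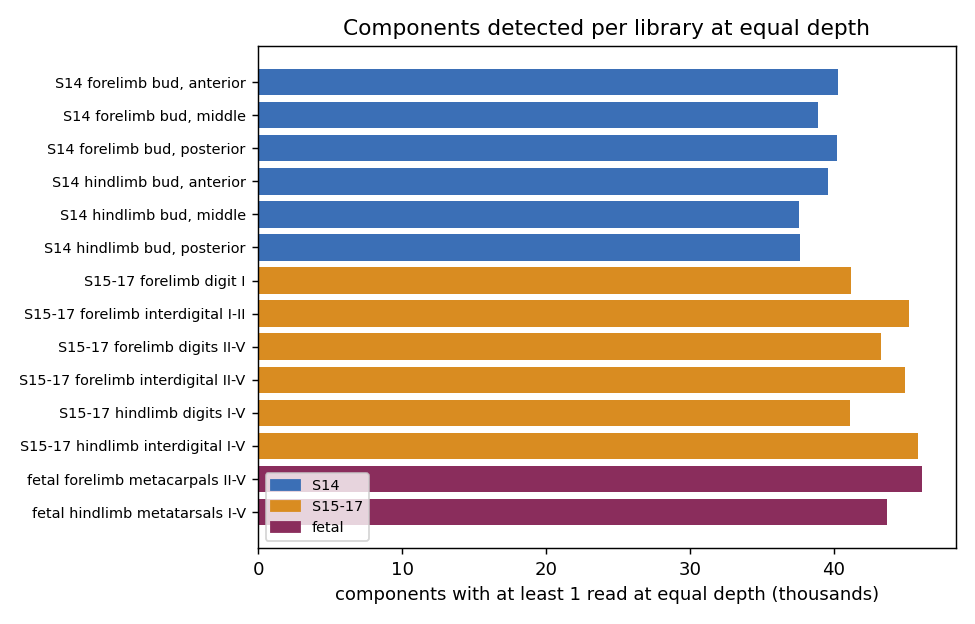
Number of components with at least 1 read in each library after thinning all libraries to 4550754 reads; bars start at 0 and colour gives the stage. Interdigital libraries reach 44976 to 45879 components and the S15-17 digit libraries 41139 to 43277.

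Parts that form the wing, forelimb digits II-V and the tissue between them, differed from the average of the thumb side and the foot in 3 components, of which only comp3957_c0 also passed against each of these regions alone. Component comp3957_c0 had scores of 456 in digits II-V and 375 in the tissue between them, against 28 and 16 on the thumb side and 26 and 19 in the foot. It had scored 210 to 537 in the S14 forelimb buds and 96 to 298 in the hindlimb buds. The wing scores thus lay within the forelimb bud range, and those of the thumb side and foot below all buds. Component comp9440_c0 went the other way, with 64 and 26 in the wing region, 705 and 643 on the thumb side, and 276 and 206 in the foot. The third, comp3599_c0, was low throughout the forelimb, at 5 and 8 in the wing region and 21 and 26 on the thumb side, and high in the foot, at 1636 and 1200.

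In limma, with tissue as block, the log2 difference was 4.19 for comp3957_c0 (SE 0.27, adjusted p = 0.019), -3.26 for comp9440_c0 (SE 0.26, adjusted p = 0.039) and -4.65 for comp3599_c0 (SE 0.31, adjusted p = 0.019). An unadjusted p under 0.05 was found for 1707 components. The count was 0 without forelimb digits II-V, without interdigital tissue II-V, without hindlimb digits, without hindlimb interdigital tissue, and with no filter. It was 12 with a pseudocount of 5, 8 with upper-quartile scaling, 101 with median-centred libraries, 175 with robust shrinkage, 155 with voom, 5 against the foot alone and 2 against the thumb side alone. In limma, comp9440_c0 lost its call against the foot alone (-2.51, adjusted p = 0.12) and comp3599_c0 against the thumb side alone (-1.73, adjusted p = 0.24), while comp3957_c0 kept it against both (adjusted p = 0.042 and 0.039). The call of comp9440_c0 was also lost in limma with a pseudocount of 0.25 (-3.29, adjusted p = 0.084) and without interdigital tissue I-II (-3.08).

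Direct comparisons of 1 wing library with 1 counterpart have no replicate check. Forelimb digits II-V and hindlimb digits had an r of 0.97 across components. Among components whose mean score over the 2 libraries reached the median, comp3938_c0 and comp3599_c0 had the highest and lowest log2(score + 1) differences. Among components with a mean score of at least 50, 0.08% were over 4-fold higher in digits II-V than in hindlimb digits and 0.07% over 4-fold lower. Against digit I these shares were 0.17% and 0.15%. Interdigital tissue II-V had 0.16% over 4-fold higher and 0.53% lower than interdigital tissue I-II, and 0.14% and 0.30% against the foot. Fetal metacarpals and metatarsals lay farther apart, with 2.44% of components over 4-fold higher in metacarpals and 3% higher in metatarsals. The root mean square log2 difference of that pair was 0.92, where counting error alone gives 0.20.

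Along the anterior to posterior axis of the S14 buds, the forelimb and hindlimb differences were weakly related, with an r of 0.148 across components. limma called 0 components between anterior and posterior parts, with a smallest adjusted p of 0.947 and 793 components at an unadjusted p under 0.05. Robust shrinkage called 5 and voom on recovered reads 16. With no filter 721 were called, of which 717 had a mean score under 10. In simulated data of this design 57.6% of 4-fold changes were called, in a run with 94 calls in total. Many components were changed at once there, which eases the adjusted threshold. The share thus does not apply to a few isolated changes, and the count of 0 does not exclude them.

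Between S14 and S15-17, a large part of the kept components differed when both limbs were fitted together. Component comp4564_c0 rose from a mean of 5.83 ± 6.65 to 395 ± 315 (SD, n = 6 libraries each). Component comp18807_c0 was at 0 in all 6 S14 libraries and at 64.2 ± 42.8 later, at least 70.1-fold higher against a floor of 3 reads over the group. Component comp2547_c0 fell from 87.5 ± 21.7 to 2.5 ± 1.87, and comp21577_c0 from 69.7 ± 50.1 to 1.5 ± 2.35. Of the called components, 493 were over 4-fold higher and 149 over 4-fold lower at S15-17.

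limma with limb as covariate called 8049 components, 39.4% of those tested, 3665 higher and 4384 lower. The log2 change was 5.90 for comp4564_c0 (SE 0.63, adjusted p = 1.9e-05), 5.77 for comp18807_c0 (SE 0.46, adjusted p = 2.5e-06), -4.84 for comp2547_c0 (SE 0.41, adjusted p = 3.4e-06) and -4.72 for comp21577_c0 (SE 0.54, adjusted p = 3.2e-05). Upper-quartile scaling turned the balance to 4624 higher and 3299 lower. In fits that share no library, 92.8% of the 5493 components called in forelimb had the same direction in hindlimb, against 72.4% of all components. Both limbs called 2298 in the same direction, where independent lists would share 539, and 6 in opposite directions. These fits within each limb were chosen after seeing the data, and the hindlimb alone called 3928. The parts dissected differ between the periods, so stage and dissection cannot be separated.

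Fetal metapodials, the long bones of hand and foot, stood far from the S15-17 digits. Component comp1255_c0 averaged 11200 ± 2510 in metapodials and 6 ± 8.49 in digits (SD, n = 2 each). Component comp1375_c0 averaged 2120 ± 1000 and was at 0 in both digit libraries, at least 819-fold higher against the same floor of 3 reads. Component comp657_c0 fell from 1370 ± 287 to 12 ± 12.7 and comp775_c0 from 720 ± 75.7 to 5 ± 1.41. Of the called components, 1493 were over 4-fold higher and 1330 over 4-fold lower in metapodials.

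limma with limb as block called 6595 components, 32.28% of those tested, 2677 higher and 3918 lower. Log2 changes were 11.59 for comp1255_c0 (SE 0.80, adjusted p = 0.0091), 10.97 for comp1375_c0 (SE 0.45, adjusted p = 0.0074), -7.18 for comp657_c0 (SE 0.74, adjusted p = 0.011) and -6.92 for comp775_c0 (SE 0.34, adjusted p = 0.0077). The median log2 difference of all kept components was -0.228. With median-centred libraries 4093 were higher and 3339 lower, and with upper-quartile scaling 3126 and 3250, so the balance of directions followed the scaling. With no filter no component was called (0), and the fit has 1 residual degree of freedom before the spread is shared.

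Components that changed in the fetus tended to have moved the same way earlier. The change from S14 to the 4 S15-17 libraries outside the fetal comparison had an r of 0.24 with the fetal change, across components and with no library in common. Of the components higher in metapodials, 70.9% were already higher in those S15-17 libraries than in S14, against 47.3% of all kept components. Of those lower in metapodials, 68.9% were already lower. This relation was chosen after seeing the data.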

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

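The tests in this part that were chosen only after the result was seen are detection at equal depth, those on the fetal libraries and the ratio of parallel components. The splits of the libraries and the count of components with 5 or more reads were set before their results were seen.

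For comp4463_c0 and comp3957_c0 the forelimb minus hindlimb difference was not the same in the S14 and later pairs, by the interaction test itself (4.97 and 2.97 on the log2 scale). Every S14 pair of comp4463_c0 was lower in forelimb and every later pair higher. Of the 10 splits of the 6 pairs into 3 and 3, the real one called 2 components and the highest other 1, and 10 splits are too few for a share under 0.05 (1 of 10 as large).

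For the other comparisons, 1 of 32 within-pair swaps called as many limb components as the real 15, the highest other calling 1, and 1 of 100 splits called as many stage components as the real 8049, the highest other calling 22. The share was under 0.05 for both, though 1 of 32 is the smallest that the limb design can give. The stage splits treat the parts of 1 stage as exchangeable, so they show that libraries group by period, not why. The labels do not say whether parts of 1 stage came from the same embryo, so chance differences between embryos are not excluded. For digit against interdigital tissue the real split called 4 and the highest other 0 (1 of 10 as large). For the S14 buds the real split and all others called 0 (10 of 10). Both have too few splits for a share under 0.05.

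More components were detected in interdigital than in digit libraries. Depth as the whole cause is argued against by the difference of 3506.3 that stayed at equal depth, above its SD of 1599.6 over 3 regions. A background of single reads as the whole cause is argued against by components with 5 or more reads at equal depth, of which interdigital libraries had 1145.7 ± 669.6 more (SD, 378 to 1609, higher in 3 of 3 regions). A wider mix of cell types in interdigital tissue could give such a difference, but no gene names tie components to cell types, so this stayed untested. Differences in RNA quality also stay open.

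The fetal libraries stood apart from all others. Against depth as the whole cause, reads thinned to equal depth still gave 6881 calls. Against a few abundant components as the whole cause of the calls, 5851 were called without the 50 largest. Of these, 2897 were higher and 2954 lower, against 2677 and 3918 with all components. Most of the excess of lower calls thus went once the 50 largest were left out and the rest rescaled. Scaling also set the balance of directions, yet 5921 of 6595 components kept their call and direction with median-centred libraries. The fetal stage and the dissected part, metapodials against digits, cannot be told apart in this design, and either may account for the difference.

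The limb-called components comp1195_c0 and comp3354_c0, singled out after their values were seen, ran in parallel. They could be pieces of 1 transcript: the SD of their log2 ratio over the 12 libraries before the fetal stage was 0.24, where counting error gives 0.29. The limit set for this test, 0.95, is met by 90.7% of random pairs, and 8.95% of random pairs had an SD as low as theirs, so the test could hardly have come out the other way and decides nothing. Over all 14 libraries the SD was 0.33, and sequences that would settle the matter were not analysed here.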

How the results depend on the processing

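Voom on recovered reads, the fetal alternatives, the stage fits within each limb and all alternatives of the covariance were chosen after seeing the data. Of the alternatives to single tested components, 234 kept direction and side of the threshold and 45 kept direction but lost the call. Another 40, of ratios between single libraries with no test, stayed within their counting interval. Among counts of calls, 64 stayed within 1.5 times and 47 moved farther. The balance of higher and lower calls turned with upper-quartile scaling for stage (4624 higher, 3299 lower) and with median-centring for the fetal comparison (4093 higher, 3339 lower). For the 6 limb pairs, 6 higher and 9 lower became 6 and 2 in later stages alone. It was 5 and 3 without the anterior bud pair and 4 and 3 without the posterior. In every other limb alternative the lower calls were as many as the higher or more. The cause of the moves below was not tested. In some alternatives, fewer pairs or libraries or more components entered the test.

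For the 6 limb pairs, the count of 15 became 8 with a pseudocount of 0.25, 8 with no filter, 142 with voom, 6 with no block and 8 in later stages alone, and 6 to 12 when leaving out a pair. For the S14 buds, the count of 0 became 2 with a pseudocount of 5, 11 with median-centred libraries, 150 with robust shrinkage, 211 with voom and 8 with no block, and stayed 0 without any 1 pair. The interaction count of 2 became 0 with no filter and 0 with no block, and 0 to 7 when leaving out a pair. For digit against interdigital tissue, 4 became 0 with a pseudocount of 0.25, 0 with no filter, 0 with no block, 31 with a pseudocount of 5, 148 median-centred, 213 robust and 218 with voom, and 0 to 35 when leaving out a pair. For the wing region, 3 became 12 with a pseudocount of 5, 0 with no filter, 8 with upper-quartile scaling, 101 median-centred, 175 robust, 155 with voom and 5 against the foot alone, and 0 to 4 when leaving out a library. For anterior against posterior, 0 became 721 with no filter, 5 robust and 16 with voom, and stayed 0 without any 1 library. The stage count of 8049 became 3928 in hindlimb libraries alone, with 6961 to 7888 when leaving out a library. The fetal count of 6595 became 0 with no filter. The mean covariance of 0.0446 became 0.0293 with a pseudocount of 5, 0.0324 without the called components, and 0.0305 to 0.0619 when leaving out a pair.

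The leading limb components comp3938_c0, comp14042_c0 and comp3599_c0 kept their call under each alternative run; comp13294_c0 lost it in later stages alone (adjusted p = 0.1 in limma). Median shifts from the mean library were -0.16 and -0.19 (log2) for metacarpals and metatarsals and 0 to 0.09 for the others. Set tests with estimated correlation and count models with other size factors, planned for named genes and raw counts, were not run. No paired analysis by replicate number was possible because each part has 1 library.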

Other observations

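The test in this part was chosen after the result was seen.

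Some components looked switched on in 1 limb and off in the other. With at most 3 reads in each of the 6 libraries of 1 limb and at least 10 in each of the other, 1 component qualified, comp13294_c0, on in hindlimb. The limit of 10 reads was the first choice; with 8 reads, tried after the reads had been seen, comp14042_c0 was added, on in forelimb. Each lay exactly at its limit in its lowest library, with 10 and 8 reads. As a test of a chance split of the libraries, on from 10 reads, only 1 of the 32 within-pair swaps, the real one, gave as many, and the highest other gave 0. For a chance split of the libraries, on from 8 reads, it was likewise 1 of 32, with 0 in the highest other. With 1 or 2 components set against 0, and limits chosen with the reads in view, these counts decide nothing on whether transcripts were restricted to 1 limb. The more abundant comp3938_c0 and comp3599_c0 missed the limit because at least 1 library of the low limb held more than 3 reads.

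Fetal metacarpals and metatarsals differed by over 2-fold in 14.35% of components with a mean score of at least 50, against 1.86% to 4.63% in the 5 earlier limb pairs. Differences of the fetal pair had an r of only 0.04 across components with those of the S15-17 digits.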
